A study of Mus musculus with 2 samples.

How the data were processed

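The series holds 1 ChIP library made with an antibody against H3K9me3 and 1 control library, both from sorted intestinal stem cells of 12 pooled mice. The control carries the word input in 1 label and IgG in another, and no label states whether Setdb1 had been deleted in these mice. The ChIP library has a peak list, and the control library is seen only through its tags in those peaks. With 1 library per group and no replicate, no test between samples was made and no p-value across genes is given.

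Per the submitters' processing notes, Bowtie2 2.2.8 and HOMER 4.10.1 were used, with the builds GRCm38 and mm10. Per the file headers, the list has the columns of HOMER findPeaks. The caller's options are not given in the sources used here. The deposited normalized tag count is a coverage signal, the ChIP tags of a peak scaled to a fixed library total that the header does not state. The authors' score is the caller's own value per peak, and was used to rank and filter peaks within the list alone. The deposited fold over control is the ratio of ChIP tags, scaled to the control library, to control tags, and no peak was under 4. The deposited p-value of each peak came from the caller, with a highest value of 8.32e-05, and 35 were written as 0. Per the file headers, the control tags are a signal too, and 43.0% of peaks stood at their lowest value, 0.5 tag. A fold at that floor depends on it. Positions and widths are in bp.

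Low normalized tag counts were spaced by 0.524, the worth of 0.5 tag, and 100% of the values in the lower part of the list were whole steps within a tolerance of 0.1, so tags per peak were recovered. The control library had 0.684 of the tags of the ChIP library. If the scaling was to 10 M tags, a setting the header does not give, the libraries held 9.55 M and 6.53 M tags. The median peak rested on 16.5 tags. Intervals of tags are exact Poisson and those of shares exact Clopper-Pearson, at 95%.

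Gene positions came from a RefSeq gene table of GRCm38.p6, the same build as mm10, with 49997 genes. It gives gene spans without strand, exons or repeats, and no genome sequence was used. The design had planned promoter, exon and intron classes, gene starts and repeat classes. In their place peaks were classed by whether the centre lay in a protein-coding gene, another gene or between genes, and gene starts were replaced by either end of a gene. Repeat classes, repeat names and GC content were not analysed here. In addition, 340 genes with scaffold coordinates were left out, which left 49603 genes, 21779 of them protein-coding. Chromosome lengths were taken as the largest deposited end. The 147 peaks on scaffolds entered no position result.

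Positions were compared with 1000 circular shifts or uniform placements. Lists were compared with 10000 random lists drawn within 10 bins of gene length and by coding status, and a list was called above or below when it lay outside the central 95%. All 21 lists were fixed before the data were examined. Of the lists, 8 were built from symbol patterns, and the zinc finger list takes genes by symbol, so it includes zinc finger genes without a KRAB domain. On simulated data with 49603 genes, 5.50% of 400 lists of 30 genes with no effect fell outside the central 95%. Lists in which 25%, 50% and 100% of members were given a peak were called above random in 38.5%, 96.5% and 100% of 200 draws. The simulated peaks were placed uniformly and the simulated lists were scattered genes. These rates therefore do not cover lists of clustered genes that share peaks.

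Genes were named by a rule fixed beforehand. It took the 10 genes with most peaks, leaving out predicted genes, the 10 genes with the highest-scoring peak within 2 kb of an end, up to 4 members of each list with most peaks, and the 5 highest-scoring peaks. It always took Setdb1, Lgr5, Olfm4, Ascl2, Zbp1, Ripk3 and Mlkl. Its part on repeat names could not be used. Some genes that the rule took are not reported here. Nnat, Impact, Peg10, Mest, Meg3, Kcnq1ot1, H19, Igf2r, Plagl1, Rasgrf1, Hrh1, Atg7, Chd5, Hes2, Espn, Dazl, Tcstv3, Tubb3, Casp8, H2bc23 and Taf7l, where named, were chosen after their values were seen.

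Other settings listed beforehand were the upper part of the list by score, a fold of at least 8, autosomes alone, peaks within 5 kb merged, covered base pairs, other overlap rules, other windows, random lists matched on chromosome, and 1 list member per Mb. Alternatives chosen after the data were seen were strong peaks, weak peaks, peaks with at most 10 control tags, windows at gene ends, the nearest protein-coding gene, 50 length bins, and strong peaks under these and under the chromosome match and the thinning. For the run of peaks on chromosome 6, the criteria of the test were written after the run had been noticed. They were reworded once after its control value was known, which would have left the outcome open in place of a value inside the criterion, and the earlier wording was restored and used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.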

Results

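H3K9me3, a histone mark of silenced chromatin, was profiled by chromatin immunoprecipitation and sequencing in intestinal stem cells. The cells carried high GFP and low CD24 and were sorted from Lgr5-EGFP-IRES-CreERT2 mice with a floxed Setdb1 gene, on the C57BL/6 strain at 8 weeks of age. Lgr5 marks cycling stem cells of the crypt, and Setdb1 encodes an H3K9 methyltransferase. Cells of 12 mice gave 1 ChIP library, which was set against 1 control library that the labels describe both as input and as IgG. The labels give no second genotype and no replicate, so the design asks where the mark lies in these cells, and no difference between conditions could be tested. Positions are on GRCm38 (mm10), and intervals cover counting error alone.

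The mark was called at 40119 peaks that together covered 36.8 Mb. Of these, 39972 lay on chromosomes 1 to 19, X and Y. Most peaks were short and held few tags. The median width was 769 bp (quartiles 500 and 1030 bp), and 31.9% of peaks were exactly 500 bp wide. The median peak held 16.5 ChIP tags (exact Poisson 95% interval 9.52 to 26.6), and the authors' fold over control had a median of 12.32 and a lowest value of 4. A small part of the list carried much of the signal. The 4065 peaks with at least 50.8 normalized tags, called strong peaks here and chosen as the top 10% after the values were seen, held 40.04% of all tags in peaks. Their median width was 1923 bp, against 500 bp for the 19496 peaks below the median tag count, called weak peaks here.

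Peaks were densest on chromosome 17, at 20.6 per Mb or 1.40 times the number expected from uniform placement. Chromosomes 11, 7 and 4 followed at 19.9, 19.2 and 19.01 per Mb. The X chromosome carried 11.6 peaks per Mb, which was 0.753 of the autosomal density, and Y carried 86 peaks or 0.947 per Mb. The order did not hold for strong peaks, whose density on X was 1.09 times that on autosomes. Chromosome 4 had the highest density of strong peaks, at 1.86 per Mb, and the X chromosome had 1.66 per Mb.

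Protein-coding genes held 46.8% of peak centres (exact 95% interval 46.4 to 47.3%), and 44.7% lay between genes. In 1000 circular shifts of the peaks along their chromosomes, the share in protein-coding genes ranged from 38.2 to 42.5%, so the observed share lay above every shift. Strong peaks lay the other way. Protein-coding genes held 30.5% of strong peaks (29.1 to 32.0%), below the shift range of 36.1 to 43.5%, while 61.0% of strong peaks lay between genes. Weak peaks lay in protein-coding genes in 51.4% of cases. The number of protein-coding genes within 500 kb of a peak had a median of 11 for weak peaks and 6 for strong peaks. The shifts gave medians of 5 to 7 for weak peaks and 5 to 6 for strong peaks, so strong peaks did not lie among fewer genes than shifted positions. From the lowest to the highest 10% of peaks by tag count, the share between genes went from 39.2 to 61.0%.

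**Figure D1:**
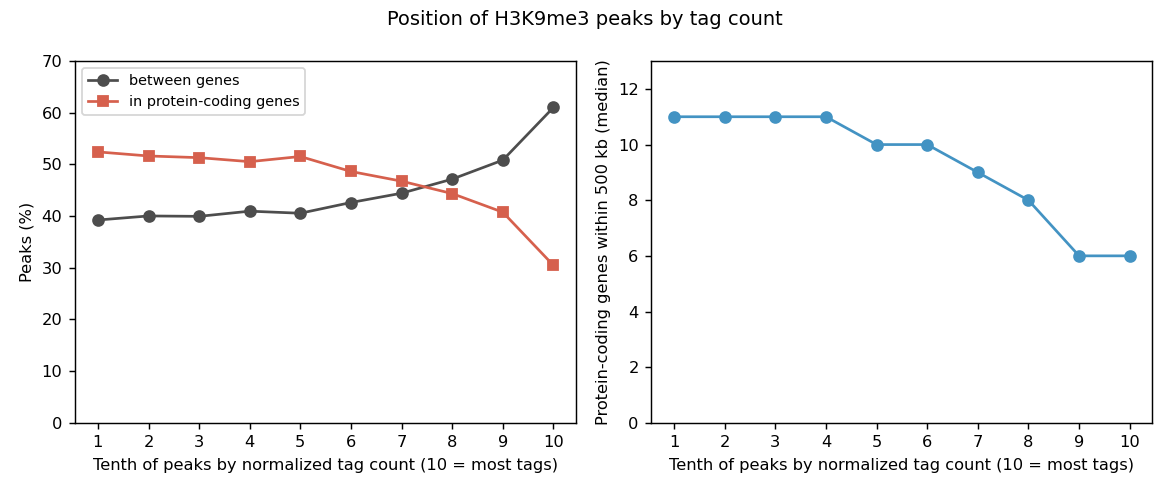
Position of peaks on chromosomes 1 to 19, X and Y, split into 10 equal groups by normalized tag count. The left panel gives the percent of peaks between genes and in protein-coding genes, and the right panel the median number of protein-coding genes within 500 kb, which was 11 in the lowest group and 6 in the highest.

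Gene ends carried peaks more often than shifted positions did. Of 39972 peaks, 19.2% (18.8 to 19.6%) lay within 2 kb of either end of a protein-coding gene, against 5.20 to 7.09% in the shifts. The share was 19.3% for weak peaks (shifts 5.08 to 7.38%) and 9.08% for strong peaks (shifts 4.61 to 6.82%), so both lay above every shift. In total 7997 protein-coding genes (36.7%) had a peak at an end, and 551 (2.53%) had a strong one. Imprinted genes (27 of 39), neuronal genes (14 of 20), clustered protocadherins (55 of 57), Hox genes (30 of 39), canonical histone genes (35 of 68) and ribosomal protein genes (44 of 85) had end peaks more often than the central 95% of matched random lists. Markers of immune cells (2 of 18), olfactory receptors (36 of 1105), vomeronasal receptors (14 of 350) and cytochrome P450 genes (15 of 74) had them less often. With 10 kb around either end, immune cell markers (percentile 37.5) and neuronal genes (91.8) came within the random range. Strand and exons were not used here, so the start and the far end of a gene are counted alike. Several clustered protocadherins end at the same position, so a peak there can count for each of them. Close neighbours in other lists can share an end peak too. Lists were not thinned by distance for these end counts, so the counts are of genes and not of separate peaks.

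At the genes with the highest-scoring end peaks, the tallest peaks had low folds over control. The tallest peak of a gene was not always its highest-scoring one. The pseudogene Rn18s-rs5, a copy of ribosomal RNA sequence on chromosome 17, had a peak of score 1031 at an end, and its tallest peak (39842469 to 39844725) held 16841.7 normalized tags beside 1585.5 control tags. Tmem267 on chromosome 13 had 8 peaks, 7 of them strong, with a highest score of 167.5 at an end. Aida and Brox on chromosome 1 shared a peak (183298983 to 183299994) of 373.0 normalized tags and a fold of 4.24. The other genes that this ranking named were Fcgr3, Mir6546 and the tRNA genes n-TDgtc3 and n-TEctc5 on chromosome 1, Speer4cos on chromosome 5 and Mid1-ps1 on Y, whose tallest peaks had folds of 4.70 to 6.04.

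The question of which genes the mark covers was addressed with 21 gene lists. A gene counted as marked when a peak touched its span or the 5 kb on either side, and 12108 protein-coding genes (55.6%) met this. Lists are placed among 10000 random lists matched on gene length and on coding status, as a description of this library. Clustered protocadherins, cell-surface proteins of neurons, were marked in 56 of 57 genes (98.2%, against a random mean of 67.5%). Imprinted genes were marked in 37 of 39 (94.9% against 58.2%), and Hox genes, which pattern the body axis, in 37 of 39 (94.9% against 52.5%). Canonical histone genes were marked in 43 of 68 (63.2% against 22.0%) and cytosolic ribosomal protein genes in 55 of 85 (64.7% against 47.8%). These 5 lists lay above the central 95% of random lists. Olfactory receptors (87 of 1105, 7.87% against 22.8%), vomeronasal receptors (59 of 350, 16.9% against 34.0%) and cytochrome P450 genes (27 of 74, 36.5% against 57.0%) lay below it.

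The remaining 13 lists lay within the random range, where chance alone would put about 1.05 of the 21 outside if members were marked independently. Intestinal stem cell markers were marked in 16 of 24 genes (66.7%, random mean 65.2%), absorptive enterocyte markers in 15 of 22 and secretory lineage markers in 13 of 28. Markers of other cells that a sort could hold showed peaks in 8 of 18 immune genes and 10 of 16 mesenchymal and endothelial genes. Necroptosis and cell death genes were marked in 17 of 28, nucleic acid sensing and interferon genes in 14 of 28, genes of H3K9 methylation and silencing in 20 of 31 and DNA damage repair genes in 9 of 20. Neuronal genes were marked in 18 of 20, germline and 2-cell-stage genes in 17 of 34, liver and muscle genes in 5 of 15, and zinc finger genes taken by symbol in 259 of 428. With members thinned to 1 per Mb, protocadherins (percentile 57.8), Hox genes (96.4) and vomeronasal receptors (3.70) came within the random range, and cytochrome P450 genes did too (54.6). With peaks given to the nearest protein-coding gene, vomeronasal receptors lay above random (1.31 times), protocadherins, whose spans overlap, below it (0.0246 times), and cytochrome P450 genes (percentile 39.5), histone genes (16.8) and imprinted genes (97.4) within the range. Under the same rule DNA damage repair genes lay below random (0.523 times) and zinc finger genes above it (1.12 times). Neuronal genes came above the range for peaks in the upper part by score (percentile 97.8) and for the gene span alone (98.5), immune cell markers below it for the gene span alone (2.00), and liver and muscle genes below it with the chromosome matched (2.14). Zinc finger genes came above it with 10 kb around either end (97.8). Among weak peaks alone, germline genes (2 of 34) and DNA damage repair genes (4 of 20) lay below random, and imprinted genes (17 of 39) and histone genes (11 of 68) lay within the range. Ribosomal protein genes came within it among peaks of at least 8-fold (81.7) and for the gene span alone (94.7).

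**Figure D2:**
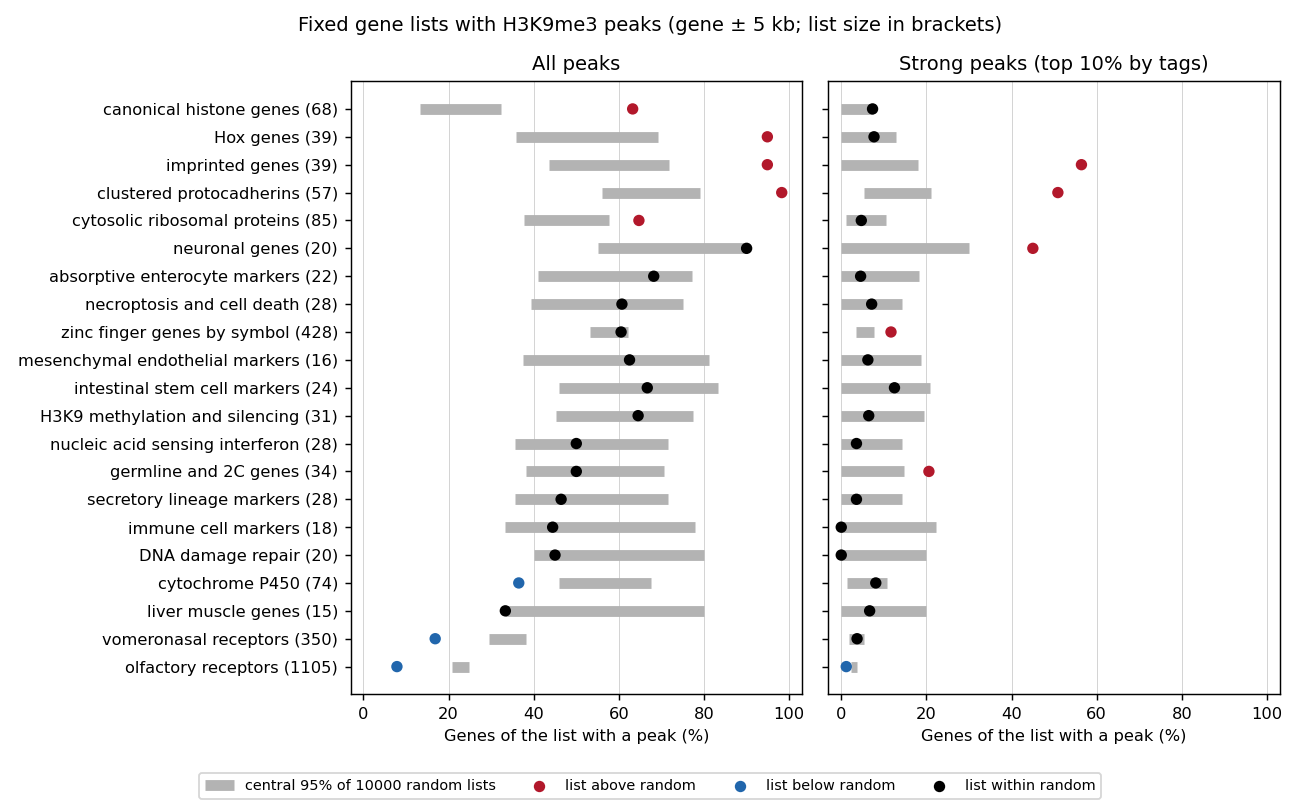
Percent of genes with a peak in each of the 21 lists, for all peaks (left) and strong peaks (right). Points are the lists, with their size in brackets, and grey bars the central 95% of 10000 matched random lists; imprinted genes stand at 94.9% on the left and 56.4% on the right.

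Strong peaks named a different set of lists. Imprinted genes led, with a strong peak at 22 of 39 genes (56.4% against a random mean of 7.92%, or 7.12 times). Clustered protocadherins followed at 29 of 57 (3.97 times the random mean), then germline and 2-cell-stage genes at 7 of 34 (3.26 times), neuronal genes at 9 of 20 (3.07 times) and zinc finger genes at 50 of 428 (2.12 times). Olfactory receptors had a strong peak at 13 of 1105 genes and lay below random, while vomeronasal receptors (13 of 350, 1.04 times) and cytochrome P450 genes (6 of 74, 1.61 times) lay within the random range. Hox genes (3 of 39), canonical histone genes (5 of 68) and ribosomal protein genes (4 of 85) lay within the random range. The germline list came within the range among strong peaks with at most 10 control tags (percentile 91.6), and zinc finger genes (89.1), protocadherins (89.5) and olfactory receptors (5.95) did so with 1 member per Mb. When length was matched in 50 bins, neuronal genes stood at 1.88 times random, and histone genes came above the range (2.94 times, percentile 98.7).

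Individual imprinted genes carried tall peaks. Several of these genes were chosen after their values were seen. Gnas on chromosome 2, which encodes a G-protein subunit, had a peak at 174295044 to 174301300 with 202.5 tags (exact Poisson 95% interval 176 to 232). Peg3 on chromosome 7 had a peak at 6727265 to 6730916 with 135.5 tags (114 to 160). Nnat (131.0 normalized tags), Impact (127.8), Peg10 (124.1), Mest (109.0) and the long non-coding RNA Meg3 (108.4) had 1 strong peak each. Snrpn had 8 peaks and Kcnq1 had 7, each with 1 strong peak, and the strong peak at Kcnq1 also lay in Kcnq1ot1. H19, Igf2r, Plagl1 and Rasgrf1 had 2 peaks each and no strong one.

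Among the other marked lists, peaks were often shared by neighbours. Pcdhga1, Pcdhga2 and Pcdhga3 on chromosome 18 each counted 29 peaks and Pcdhgb1 counted 27, with the same tallest peak (37765732 to 37768850, 134.6 normalized tags). The zinc finger gene Zfp978 on chromosome 4 had 21 peaks, 6 of them strong, and a tallest peak of 389.2 normalized tags at 147218807 to 147227780. Zfp536 had 20 peaks, Zfp469 had 15 and Zfp993 had 14. In the Hox clusters, Hoxa3 had 7 peaks with a tallest of 34.6 normalized tags, and Hoxb3 and Hoxd3 had 5 each, with tallest peaks of 71.2 and 37.7. The histone genes H1f1, H3c1 and H4c1 shared a tallest peak of 21.5 normalized tags, while the tallest was 50.8 at H2bc6 and 192.8 at H2bc23. Cntnap2 (17 peaks), Csmd1 (14), Dlg2 (12) and Rbfox3 (10), long genes of neurons, had at least 1 strong peak each. Rpl18 had 5 peaks, and Rpl19, Rplp2 and Rps15 had 3 each.

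At the stem cell genes, no peak was called over Setdb1 or Olfm4, a stem cell marker, or within 5 kb of either. Lgr5 on chromosome 10 had 4 peaks, none of them strong. The tallest lay inside the gene (115586282 to 115587229, 21 tags, 13 to 32.1), and its fold of 28.74 rested on the lowest control value, 0.5 tag. Ascl2, a transcription factor of crypt stem cells, had 1 strong peak that touched the gene (142967628 to 142969837 on chromosome 7, 66 tags, 51.0 to 84.0, fold 6.45 with 7 control tags). Ephb2 had 9 peaks, Msi1 had 7, and Axin2 and Rnf43 had 5 each. Of the necroptosis genes, Zbp1 (11.5 tags, 5.84 to 20.3), Ripk3 (11.5 tags) and Mlkl (10 tags, 4.80 to 18.4) had 1 peak each, close to the lowest count in the list, 9 tags. Tnfrsf1a had 5 peaks, Bak1 had 4 and Pmaip1 had 3. Irf7 and Stat2 had 4 peaks each in the nucleic acid sensing list, and Dnmt3a, Ehmt2 and Kdm4a had 5 each in the silencing list.

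The genes with the most peaks included immunoglobulin loci. The immunoglobulin light chain locus Igk on chromosome 6 had 61 peaks, 6 of them strong, and the heavy chain locus Igh on chromosome 12 had 37, also with 6 strong. Gse1 had 51, Tiam1 had 42, Snhg14 had 30 with 8 strong, Pcdhga1, Pcdhga2 and Pcdhga3 had 29 each, and Camta1 had 28. Counts of peaks per gene were not corrected for gene length.

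Peaks lay closer together than uniform placement would put them. The next peak was within 10 kb for 29.0% of peaks, against 15.3 to 16.3% in 1000 uniform placements, and for 9.13% of strong peaks, against 1.24 to 2.56%. With peaks within 5 kb merged, which removes the shortest gaps, the share was 12.2%, or 0.949 times uniform. Without merging, the share of all peaks was 2.17 times uniform at a distance of 5 kb, 1.84 at 10 kb and 1.15 at 50 kb. Most of the windows of 1 Mb with the most peaks held many genes. The window at 152 to 153 Mb of chromosome 4, with Chd5, Hes2 and Espn, held 132 peaks, and the windows at 81 to 82 Mb and 80 to 81 Mb of chromosome 10 held 130 and 126 peaks with 51 and 54 protein-coding genes. The window at 153 to 154 Mb of chromosome 4 was an exception, with 100 peaks and 4 protein-coding genes. By strong peaks the order differed. The window at 114 to 115 Mb of chromosome 6 held 30 strong peaks and 6 protein-coding genes, among them Hrh1 and Atg7, and the window at 55 to 56 Mb of chromosome 8 held 24. The window at 152 to 153 Mb of chromosome 4 held 16 strong peaks.

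The 30 strong peaks of chromosome 6 belonged to 1 run of 44 peaks between 114496441 and 114637535, a stretch of 141 kb in which no gap exceeded 10 kb. No gene of the table used overlapped it, and the nearest protein-coding genes, Hrh1 and Atg7, ended 13143 bp before it and began 5592 bp after it. Peaks covered 45.0% of the stretch. The summed tags were 7.54 times the control, below the median of 10.4 for the other 71 runs of at least 10 peaks. Among the runs with the next most strong peaks, the fold was 5.20 (chromosome 8, 18 strong peaks), 6.58 (Y, 15) and 12.6 (chromosome 8, 12). The control itself held 305 tags over the peaks of the run, or 4.80 per kb (exact Poisson 95% interval 4.28 to 5.37).

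**Figure D3:**
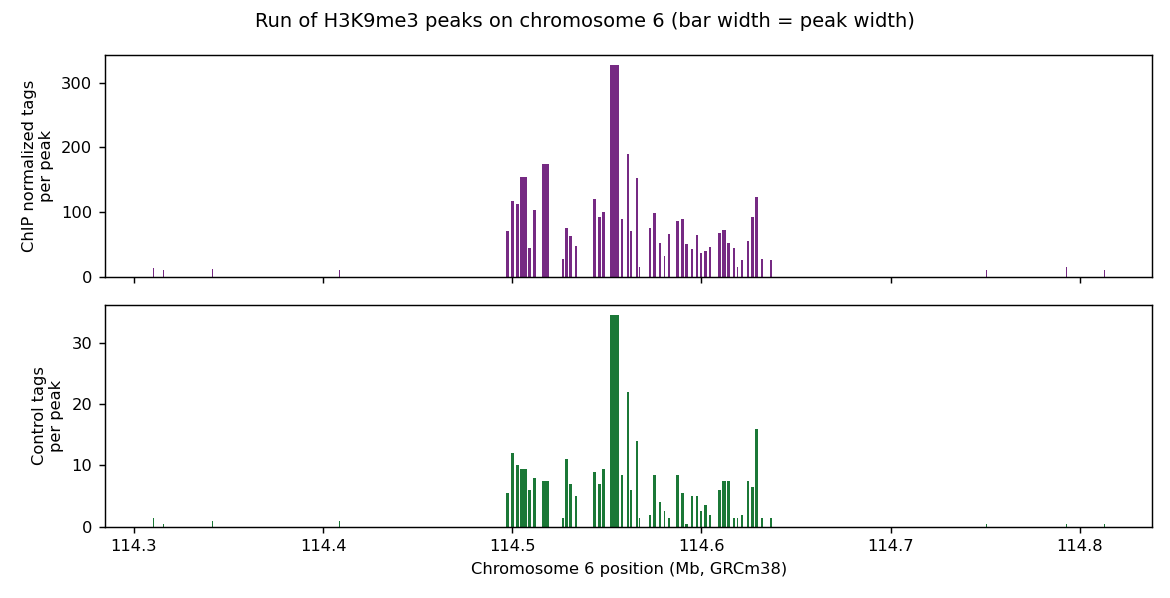
Peaks of the chromosome 6 run and 200 kb on either side, as ChIP normalized tags per peak (top) and control tags per peak (bottom) against position in Mb on GRCm38; bar width is peak width. The tallest peak of the run holds 326.9 normalized tags and 34.5 control tags, and the peaks outside it hold at most 14.7 and 1.5.

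By the authors' score, peaks between genes had a median of 11.5 and peaks in protein-coding genes a median of 11, and their normalized tag counts were 18.9 and 16.2. The 5 highest-scoring peaks lay on chromosome 14 (124801346 to 124802265, score 1250), chromosome 18 (90601968 to 90602660, 1085.5), chromosome 17 (39848375 to 39848875, 1031), chromosome 19 (61330927 to 61331587, 784.5) and chromosome 15 (75086452 to 75087452, 672). Of these, the peak on chromosome 17 had an annotated gene within 5 kb, Rn18s-rs5. Those on chromosomes 14, 18 and 19 were the last peak of their chromosome. Their control counts were high, at 290 to 861 tags.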

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

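Of the tests in this part, those on the chromosome 6 run, on control tags at weak peaks and on the highest-scoring peaks were chosen after the result was seen, and the test of gene ends was written before. The design has no contrasting group, so no biological explanation was tested for any pattern.

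A signal lay outside the positions used in the comparisons. The 147 peaks on 29 scaffolds had a median fold over control of 9.81 and a highest fold of 34.9.

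The control library held 4.80 tags per kb over the run of 44 peaks on chromosome 6. The median was 1.10 per kb over all peaks, many of them at the lowest control value, and 2.12 per kb over strong peaks. Extra copies of this sequence in the cells, beyond the reference, may raise both libraries. The value stood at percentile 91.1 of 123 blocks of 30 consecutive strong peaks elsewhere (median 2.33 per kb). The run's 30 strong peaks alone, at 5.43 per kb, stood at percentile 94.3. Both are inside the central 95% set for the mark on a usual amount of DNA. Both were above the median and below the upper bound of 7.22 per kb, so extra copies are neither shown nor excluded. The blocks were chosen by tag count and not by amount of DNA, so lying inside their range cannot show a usual amount. Nor were they limited in length, so they do not match a run of 141 kb. Among the other 71 runs of at least 10 peaks, the run stood at percentile 90.1. The control of those runs had a median of 1.46 tags per kb and an upper bound of 20.1. If the scaling was to 10 M tags, the run held 2.00 times the genome-wide control tags per kb, 2.40.

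Weak peaks lay among more genes than strong peaks, with medians of 11 and 6 protein-coding genes within 500 kb. A control at its lowest value, 0.5 tag, could have let such peaks through. The 5894 weak peaks with 1 or more control tags also had a median of 11 nearby genes. The pattern was therefore not limited to peaks at the lowest value. Those peaks stood above that value by selection, so they do not test the 13556 weak peaks at it. Weak peaks held few ChIP tags and every peak passed a lowest fold over control, so their control counts were low in any case. The split therefore cannot decide whether sparse control counts let such peaks through. Uneven recovery of DNA at gene ends remains open. It needs weak peaks to lie at gene ends more often than strong peaks and than any shift. The share was 19.3% for weak peaks, against 9.08% for strong peaks and at most 7.38% in the shifts. Over all peaks it was 19.2%, so lying at gene ends did not set weak peaks apart from the list as a whole. The mark itself at gene ends would give the same share, and GC content was not tested.

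The highest-scoring peaks stood where the control was also high. The 20 highest had a median of 69.9 control tags per kb, where the 99th percentile of all peaks was 6, and their median fold was 4.785 against 12.32 in the whole list. This is consistent with reads of many sequence copies being placed on 1 reference copy. Whether the mark also lies on these sequences was not tested.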

How the results depend on the processing

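Results for strong peaks, weak peaks, at most 10 control tags, gene-end windows of 10 kb, the nearest protein-coding gene and 50 length bins were chosen after the data were seen. No paired analysis was possible because there was 1 library per group. Repeat classes, exon classes and gene starts were not run. Over all lists and settings, 317 list comparisons kept their call against the central 95%. The ratio to random stayed on its side of 1 in 282 of them and crossed it in 35, for lists within the random range under both settings. Another 20 came within the range with the ratio on its side of 1, and 18 left the range without turning. In 23 the ratio crossed 1 and the call changed. Most of these 23 came within the range, while the germline list among strong peaks left it. Only vomeronasal receptors and protocadherins went from 1 side of the range to the other, with peaks given to the nearest protein-coding gene. Of the 317 kept calls, 21 came from merging peaks within 5 kb, which left every list ratio the same. A further 21 came from dropping the 344 peaks with over 10 control tags, a small part of the list. Imprinted genes came within the random range with weak peaks (1.10 times, percentile 69.8) and the nearest protein-coding gene (1.22 times, percentile 97.4), and their ratio ran from 1.10 to 7.29, while that of olfactory receptors stayed at or under 0.721. Except where a construction is named, the cause of a change was not tested. The upper part of the list by score kept 23771 peaks, with 5321 genes marked at an end and an X to autosome density of 0.848. That density was 0.819 with peaks within 5 kb merged and 0.832 by covered base pairs. Merging turned clustering from 1.84 to 0.949 times uniform, since it removes gaps of up to 5 kb. Strong peaks (4065, median width 1923 bp) turned the share in protein-coding genes from 1.16 to 0.771 times the shifts and the X density from 0.753 to 1.09, marked 551 genes at an end and put 1 list below random. Weak peaks (19496, median width 500 bp) gave an X density of 0.564, 4274 genes at an end, 3 lists above random and 5 below. With 1 member per Mb, 3 lists lay above random and 1 below, and cytochrome P450 genes stood at 1.03 times random. Assigning peaks to the nearest protein-coding gene put protocadherins at 0.0246, since overlapping spans give a shared peak to 1 gene, histone genes at 0.848 and vomeronasal receptors at 1.31. Among strong peaks, vomeronasal receptors were at 1.04 times random, ribosomal protein genes at 0.898, cytochrome P450 genes at 1.61 and germline genes at 3.26. The same 4 lists were at 1.21, 0.831, 1.498 and 3.36 with 50 length bins, and at 1.11, 0.847, 1.52 and 2.99 with the chromosome matched, each with 1 list below random. With strong peaks and 1 member per Mb they were at 1.62, 0.755, 2.27 and 3.41, Hox genes and histone genes were at 0, and 3 lists lay above random and 0 below. Strong peaks with at most 10 control tags put cytochrome P450 genes at 1.75, with 1 list below. The lowest count in the list was 9 tags and the median 16.5, and the effect of depth was not tested.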

Other observations

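The lists and genes in this part were examined after the results were seen. Single genes outside the lists above random also carried strong peaks. Casp8 on chromosome 1, a brake on necroptosis, had 1 strong peak inside the gene (58816344 to 58819160 on GRCm38) with 105 tags (exact Poisson 95% interval 85.9 to 127), while Zbp1, Ripk3 and Mlkl had at most 12.0 normalized tags. The necroptosis and cell death list as a whole had a strong peak at 2 of 28 genes, within the random range. Among intestinal stem cell markers 3 of 24 had a strong peak, and among immune cell markers 0 of 18.

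Among germline and 2-cell-stage genes with strong peaks, Duxf3 on chromosome 10 had a tallest peak of 1330.5 normalized tags with 62.5 control tags, and Tcstv3 on chromosome 13 had 1108.9 with 174 control tags and a fold of 4.16. Dazl, a gene of germ cells, had 133.0 normalized tags with 9 control tags, Taf7l had 97.4 with 13, Sycp1 had 57.1 with 8.5, and Tex11 had 55.5 with 1. The list had few weak peaks, at 2 of 34 genes against a random mean of 36.5%. Tubb3, a tubulin of neurons, had 507.1 normalized tags in a peak outside the gene (123426973 to 123434746 on chromosome 8) with 15 control tags and a fold of 22.08. The gene ends at 123422015, so this peak touched only the far edge of the 5 kb window, and most of it lay beyond.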
